A study of Mus musculus with 6 samples.

How the data were processed

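RNA of bone marrow mesenchymal progenitors sorted from wild type and Lama4-/- mice was amplified with the SMART-Seq v4 kit for low input, made into Nextera XT libraries and sequenced as 75 bp single-end reads, per the labels' protocols. The kit amplifies full-length cDNA from the poly(A) tail before fragmentation and does not mark strand, so overlapping and antisense genes cannot be told apart, and coverage of long transcripts depends on the length of intact RNA and cDNA. The submitters' processing notes name FastQC 0.11.8, MultiQC 1.7, STAR 2.6.1d, featureCounts, Subread and DESeq2, and the builds GRCm38 and mm10; the parameters of these tools are not given in the sources used here.

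The authors deposited 1 table for the series with 25491 genes. Its blocks of per-library columns are headed raw and normalized, and the values show that the 2 headings are exchanged. The block headed normalized holds whole numbers in 100% of its cells, with different totals in each library, and was used here as the raw gene counts deposited by the authors. The block headed raw holds a deposited signal, those counts multiplied by a constant for each library between 0.708 and 1.98, and entered no test. Per the file headers the remaining columns are the authors' DESeq2 Wald test of Lama4-/- against wild type with a beta prior. They hold a mean signal, a log2 fold change shrunken by the authors with its standard error on the log2 scale, a Wald score, and a p-value with its adjusted p-value. The deposited adjusted p-value is NA for 15311 genes, left as NA here. Of the gene identifiers, 25458 (99.9%) were found in the GENCODE annotation of the same build, GRCm38, which supplied positions, overlaps and the length of the longest annotated transcript.

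Library totals ran from 6263830 to 15663957 counts. No pair of libraries of 1 genotype agreed within counting noise (chi-square per gene of 46.4 or more), so none was taken as the same library deposited again; this does not show that they came from separate mice. Genes were kept with edgeR's filterByExpr by genotype, which left 14465. In R 4.3.3, counts were scaled with TMM, and the genotypes compared with the robust quasi-likelihood F test of edgeR 4.0.16, 3 libraries against 3 with no covariate, with Benjamini-Hochberg adjustment over all tested genes at a threshold of 0.05. The common dispersion was 0.393. CPM values are counts scaled to the TMM-adjusted library total, and means are given ± SD over 3 libraries. 41 gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 where at least 5 genes were tested, which left 40 lists, with camera at an estimated correlation and with fry beside it. A list's median is over its tested genes. The lists, tests and alternatives were set before the data were examined.

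Named genes followed a rule set at the same time. It takes 18 genes of the niche, laminin and lineage; among genes past the threshold with a mean CPM of at least 5, groups that do not overlap and a symbol that is not a predicted gene or clone, the 10 largest changes in each direction; where none passes, the 5 smallest p in each direction as values only; up to 4 members of each list past the set test with the smallest p in its direction; the sort gate and sex-linked genes; and the 2 most abundant genes of each marker list of another cell type. Since Lama4 alone passed, the 5 smallest p in each direction were taken apart from it, a reading settled after the values were seen. 1 gene taken by the rule is not reported here.

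Alternatives were DESeq2 size factors and upper-quartile scaling in edgeR, no filter, a filter of 5 CPM in 3 libraries, DESeq2 1.42.0, limma voom with sample quality weights, no robust moderation, the replicate number as a block, each library left out, dominant gene classes left out, an adjusted p of 0.10 and a test against a fold of 1.5. The removal of a length trend was added after seeing the data: a lowess curve (span 0.3) of each library's log2 deviation on log10 transcript length entered the edgeR fit as an offset. The procedures were tested on simulated counts of the same means, dispersions and depths. In the simulated comparison of Lama4-/- with wild type over 13694 genes, 47 of 100 genes changed 4-fold and 85 of 100 changed 16-fold were recovered, with 1 false call. A list shifted by -0.9 on the log2 scale was called in 10 of 10 simulations over 14465 genes, and a simulated length trend with a rho of -0.420 was reduced to -0.00685. That simulated trend put 1 list past the set test before its removal and 0 after. It was a straight slope of -1 on the log2 scale per 10-fold length. The real trend was steeper among long transcripts: the median log2 fold change was 0.34 at 678 bases, -0.08 at 3390 and -0.92 at 8073.5. The run therefore does not show how many lists a trend of that shape would put past the set test. The simulated genes vary independently, so these runs do not test the correlation between genes. The run with changed genes also held no length trend, so its shares recovered need not hold for the real libraries.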

Results

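The series measured RNA from mesenchymal progenitor cells of mouse bone marrow, the stromal cells that support blood formation and give rise to bone, cartilage and fat. The cells were sorted as negative for the blood, red cell and endothelial markers CD45, TER119 and CD31 and for CD44 and SCA1, and positive for the integrin chain CD51. They came from C57BL/6J mice aged 14 weeks, 6 weeks after a sublethal dose of 7 Gy of radiation. 3 libraries were from wild type mice and 3 from Lama4-/- mice, which lack the laminin alpha 4 chain, a subunit of basement membrane laminins. The wild type libraries held 13047466, 6263830 and 13409177 counts and the Lama4-/- libraries 15663957, 12979711 and 14068457. The 10 most abundant genes took between 24.3% and 29.9% of the counts of a library. Pearson's r of log2 CPM across genes was 0.786 to 0.894 between libraries of 1 genotype and 0.768 to 0.903 between genotypes; genes are not independent replicates. The labels do not say that each library came from a separate mouse, so p-values measure the spread between these samples, which may be technical. The comparison asks which transcripts differ in the regenerating stroma when the laminin chain is missing.

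The targeted gene was read first, as a check of the labels. Lama4 (chromosome 10, 38965515 to 39110188, plus strand, GRCm38) was counted in every wild type library, at 39.9 ± 5.82 CPM (SD, n = 3), and had 0 counts in each of the 3 Lama4-/- libraries. The wild type libraries held 1281 Lama4 counts together. With 3 counts over the Lama4-/- group as the floor, Lama4 was at least 581-fold lower in Lama4-/- (edgeR quasi-likelihood test, adjusted p = 0.0497). Intervals and floors cover counting error only. That adjusted p lay at the threshold and was above 0.05 when any library but Lama4-/- replicate 3 was left out, reaching 0.593 without wild type replicate 3.

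Lama4 alone of 14465 tested genes passed an adjusted p of 0.05 in the edgeR test, and 0 genes were higher in Lama4-/-. At an unadjusted p under 0.05 there were 1851 genes, 644 higher and 1207 lower in Lama4-/-, where 723 would be expected by chance. The balance of directions was not stable: it was 988 higher and 967 lower with upper-quartile scaling, and 714 higher and 456 lower with the length trend removed. The number of calls differed between tools and filters. edgeR without a filter called 12 of 25491 genes. DESeq2 with its own filtering, on 25358 genes, called 741, 173 higher and 568 lower. On the 14465 genes limma voom called 0, with 2352 at an unadjusted p under 0.05. The authors' deposited table lists 675 genes with an adjusted p under 0.05, 191 higher and 484 lower; all 675 had the same direction and an unadjusted p under 0.05 in the edgeR fit.

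Apart from Lama4, the genes with the smallest unadjusted p did not pass the adjustment in the edgeR test. They are given as values (mean ± SD, n = 3), with wild type first and Lama4-/- second here and below. On the lower side, the transcriptional coregulator Zmiz1 was at 163 ± 41.2 against 32.2 ± 6.62 CPM with a log2 fold change of -2.34 (SE 0.27). Atxn7, a subunit of the SAGA complex, was at 43.4 ± 12.4 against 6.66 ± 0.820 CPM. Fndc3b was at 495 ± 111 against 154 ± 19.97 CPM. Fn1, which encodes fibronectin, was at 6108 ± 416 against 1986 ± 449 CPM, and coagulation factor F5 at 138 ± 23.5 against 39.1 ± 8.82 CPM. On the higher side, the clock-output transcription factor Dbp was at 14.98 ± 1.42 against 54.5 ± 4.73 CPM with a log2 fold change of 1.87 (SE 0.25). Cebpb, a transcription factor of adipocyte and myeloid differentiation, was at 19.6 ± 6.65 against 309.8 ± 181 CPM with a log2 fold change of 3.99 (SE 0.53). Its exons overlap those of Tmem189, and the kit does not mark strand. Alad, an enzyme of haem synthesis, was at 20.8 ± 5.24 against 64.5 ± 8.72 CPM. Lemd2 was at 42.2 ± 5.55 against 126 ± 38.4 CPM and the kinase Dapk3 at 11.98 ± 6.01 against 49.8 ± 2.43 CPM. The transcripts of the 5 lower genes were long, between 6853 and 8315 bases. Their log2 fold changes were smaller with the length trend removed, Zmiz1 at -1.47, Atxn7 at -1.92, F5 at -0.99, Fndc3b at -0.90 from -1.69 and Fn1 at -0.70 from -1.62, while Dbp was at 1.61 and Cebpb at 3.71. The adjusted p of the 10 genes in the edgeR test ran from 0.192 to 0.237. The call depended on the tool: with DESeq2 all 10 passed, at an adjusted p from 2.02e-13 for Cebpb to 1.21e-04 for Dapk3 and Lemd2.

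**Figure D1:**
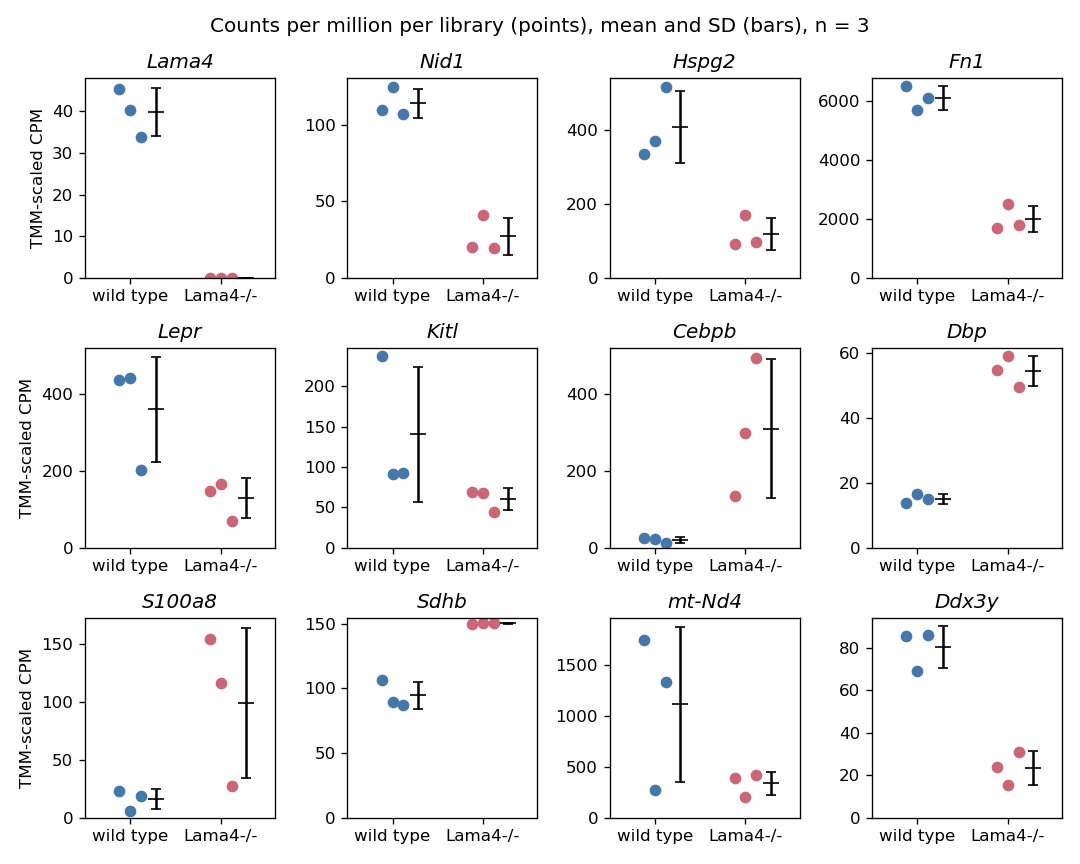
Each panel plots 1 gene, with the TMM-scaled CPM of each library as points on a linear axis from 0, wild type in blue and Lama4-/- in red, and the mean and SD of 3 libraries as black bars. Lama4 has 0 counts in all 3 Lama4-/- libraries, and the other genes shown did not pass the adjusted threshold in the edgeR test.

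Fold changes followed transcript length. Across 14458 tested genes, Spearman's rho of the log2 fold change with the longest annotated transcript was -0.46, and the median log2 fold change went from 0.34 in the decile of genes with the shortest transcripts to -0.92 in the decile with the longest. The trend was negative in each of the 9 pairs of a wild type and a Lama4-/- library, between -0.28 and -0.42. Each list past the set test below is therefore also given with this trend removed from every library, an alternative chosen after seeing the data.

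**Figure D2:**
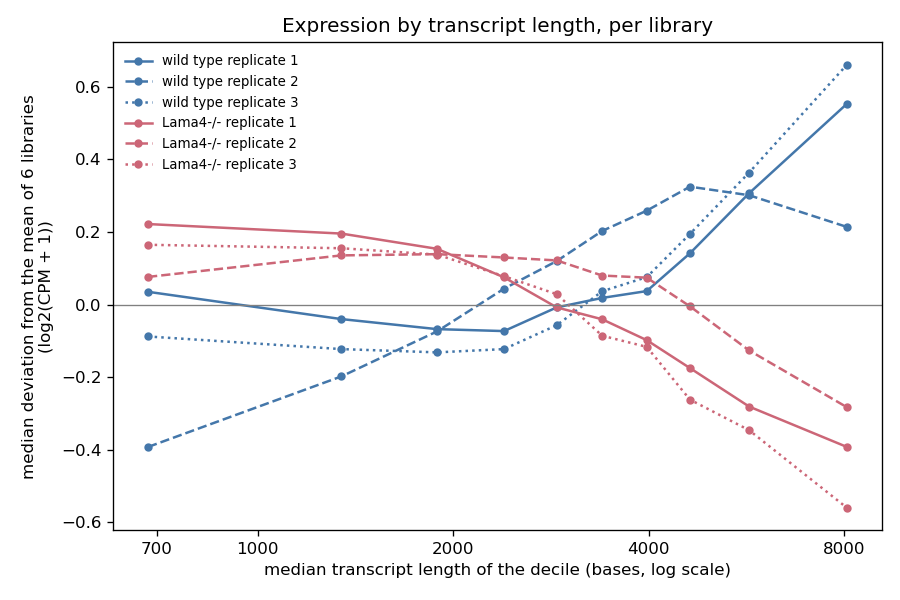
Tested genes were divided into deciles by transcript length; the horizontal axis gives each decile's median length in bases on a log scale, and the vertical axis the median deviation of each library from the mean of the 6 libraries in log2(CPM + 1). In the longest decile the wild type libraries lie at 0.55, 0.21 and 0.66 and the Lama4-/- libraries at -0.39, -0.28 and -0.56.

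Of 40 gene lists fixed before the data were examined that had at least 5 tested genes, 15 passed the set test, 6 higher and 9 lower in Lama4-/-. These calls rest on the preset correlation between genes of 0.01: 0 of the 15 held with an estimated correlation, and 0 passed fry's directional test after adjustment, where 8 of the 40 lists had an unadjusted p under 0.05. With the length trend removed, 8 of the 15 held in the same direction and 7 did not. Another 2 lists then passed, both lower in Lama4-/- (camera adjusted p = 0.0474 for each). These were immediate early genes, at a median of -0.18, and the senescence and secretory phenotype, at -0.27. In the edgeR test no single member of any list passed the adjustment over all genes. DESeq2 called members of several lists, among them 5 lower basement membrane genes, 7 lower interstitial matrix genes and 5 higher neutrophil and monocyte markers.

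Basement membrane genes other than laminins fell in Lama4-/-: 20 of 23 tested members had a negative log2 fold change, with a median of -0.89 (camera adjusted p = 1.54e-05; adjusted p = 0.547 with an estimated correlation). The linker protein nidogen 1 (Nid1) was at 114 ± 9.44 CPM in wild type and 26.9 ± 12.3 CPM in Lama4-/-. Perlecan (Hspg2) was at 406 ± 97.3 against 118 ± 43.5 CPM. The type IV collagen chains Col4a1 and Col4a2 were at 252 ± 84.4 against 99.3 ± 3.58 CPM and 163 ± 35.4 against 63.99 ± 19.3 CPM. 7 members had an unadjusted p under 0.05 on the lower side and 0 on the higher, and 6 passed when adjusted over the list alone. The summed mean CPM of the tested members, in which abundant genes weigh most, did not fall, at 45850 in wild type and 53826 in Lama4-/-. The members were long, with a median transcript of 5595 bases, and without the length trend the median was -0.39 (adjusted p = 0.0243). The log2 fold change of Nid1 went from -2.08 to -1.44 and that of Hspg2 from -1.78 to -0.54. Col4a1 went from -1.35 to -0.62 and Col4a2 from -1.35 to -0.65. All 9 tested chains of the other laminins had a negative log2 fold change, with a median of -0.85, but the list did not pass (camera adjusted p = 0.0580). It passed without a filter (adjusted p = 0.0419), with a filter of 5 CPM in 3 libraries (0.0460), with the replicate block (0.0311) and with 4 of the 6 libraries left out singly (0.0123 to 0.0364), all at the preset correlation. Without wild type replicate 2 the adjusted p was 0.269 (median -0.63), and without Lama4-/- replicate 3 it was 0.367 (median -0.53). The adjusted p was 0.565 with an estimated correlation and 0.243 with fry. With the length trend removed its median was -0.22 (adjusted p = 0.480). Among them Lama5 was at 7.79 ± 2.20 against 2.31 ± 3.99 CPM, where only Lama4-/- replicate 2 held counts, at 6.92 CPM. Lamb1 was at 60.1 ± 18.9 against 33.9 ± 14.2 CPM and Lamc1 at 58.9 ± 15.1 against 28.1 ± 14.5 CPM. Integrins and other laminin receptors fell, with a median of -0.65 over 27 genes (camera adjusted p = 0.00291; adjusted p = 0.565 with an estimated correlation). Dystroglycan (Dag1) was at 193 ± 36.3 against 93.5 ± 11.5 CPM. The collagen-binding integrin chains Itga11 and Itga10 were at 90.1 ± 20.03 against 41.5 ± 12.99 CPM and 44.4 ± 22.7 against 18.3 ± 4.39 CPM. 1 member passed when adjusted over the list alone. Their call was lost without wild type replicate 2, where the median was -0.25 (adjusted p = 0.113), and with the length trend removed, where it was -0.12 (adjusted p = 0.208).

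Genes of the interstitial matrix and collagen processing fell, 31 of 42 with a negative log2 fold change and a median of -0.57 (camera adjusted p = 3.65e-05; adjusted p = 0.547 with an estimated correlation). Besides Fn1, the fibrillin gene Fbn1 was at 214 ± 72.8 against 57.3 ± 1.63 CPM. The type VI collagen chain Col6a3 was at 1218 ± 314 against 430.2 ± 93.6 CPM, and thrombospondin 1 (Thbs1) at 1466 ± 482 against 499.9 ± 99.4 CPM. 6 members passed when adjusted over the list alone. The summed mean CPM of the tested members was 141137 in wild type and 133619 in Lama4-/-. With a median transcript of 5059 bases, this list lost its call with the length trend removed, at a median of -0.15 (adjusted p = 0.282). Without wild type replicate 3 its median was -0.29. Targets and regulators of TGF-beta and BMP signalling fell by a median of 0.34 on the log2 scale over 42 genes (camera adjusted p = 0.0164; adjusted p = 0.565 with an estimated correlation). The receptors Tgfbr1 and Bmpr2 were at 48.9 ± 2.98 against 22.1 ± 4.90 CPM and 63.7 ± 41.2 against 14.02 ± 4.002 CPM. The coreceptor Tgfbr3 was at 158 ± 40.9 against 61.1 ± 18.8 CPM and the activin subunit Inhba at 34.8 ± 20.4 against 6.97 ± 1.49 CPM. 4 members passed on the lower side when adjusted over the list alone, and 1 on the higher. This call was lost without wild type replicate 1 (adjusted p = 0.102), without Lama4-/- replicate 1 (0.150) and without Lama4-/- replicate 2 (0.0565), with medians of -0.23, -0.31 and -0.34. It was also lost with the length trend removed, where the median was -0.09 (adjusted p = 0.248).

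Identity genes of CXCL12-abundant, LEPR-positive stroma, the marrow population that makes most niche factors, fell in Lama4-/-, 20 of 24 with a negative log2 fold change and a median of -0.53 (camera adjusted p = 8.83e-04; adjusted p = 0.565 with an estimated correlation). The leptin receptor gene Lepr was at 361 ± 137 CPM in wild type and 128 ± 52.2 CPM in Lama4-/-. The PDGF receptor genes Pdgfra and Pdgfrb were at 109.7 ± 25.1 against 57.8 ± 6.74 CPM and 268 ± 89.8 against 109 ± 26.7 CPM. Zeb2 was at 69.2 ± 23.9 against 32.9 ± 5.52 CPM. Without the length trend the log2 fold change went from -1.08 to -0.03 for Zeb2 and from -0.92 to -0.13 for Pdgfra. It went from -1.30 to -0.75 for Pdgfrb and from -1.50 to -0.95 for Lepr. Of the list, 8 members had an unadjusted p under 0.05 and 0 passed when adjusted over the list alone. The median transcript was 4571 bases. The call was lost without wild type replicate 1 (adjusted p = 0.102) at a median of -0.47, and with the length trend removed, at -0.26 (adjusted p = 0.120). The list of haematopoietic niche factors did not pass (camera adjusted p = 0.139, median -0.42, and -0.24 with the length trend removed). Within it, Igf1 was at 94.6 ± 12.4 against 35.8 ± 9.65 CPM and stem cell factor (Kitl) at 141 ± 83.8 against 60.3 ± 14.01 CPM, with every wild type library above every Lama4-/- library in both. Wild type replicate 1 carried much of the Kitl mean, at 237 CPM beside 91.4 and 92.9, and without it the log2 fold change went from -1.22 to -0.60. Removing the length trend took the log2 fold change from -1.40 to -0.61 for Igf1, to -0.64 for Kitl and from -0.55 to 0.02 for Cxcl12. Cxcl12, the chemokine that retains haematopoietic stem cells, was at 7569 ± 3269 against 5177 ± 1291 CPM. Angpt1 was at 33.7 ± 2.81 against 20.9 ± 12.04 CPM and Csf1 at 262 ± 124 against 184 ± 49.3 CPM. Vcam1 was at 395 ± 94.9 against 282 ± 81.3 CPM and Il7 at 30.3 ± 19.4 against 34.5 ± 7.85 CPM. Osteopontin (Spp1) was at 5416 ± 857 against 8713 ± 3489 CPM. The groups of these last 6 genes overlapped. None of these 8 genes passed the adjustment in the edgeR test, while Igf1 alone passed with DESeq2 (adjusted p = 0.000603).

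Among lineage lists, chondrocyte differentiation fell, 16 of 22 genes with a negative log2 fold change and a median of -0.32 (camera adjusted p = 0.00544; adjusted p = 0.651 with an estimated correlation). Aggrecan (Acan) was at 3109 ± 641 against 1120.4 ± 405 CPM and Col11a1 at 6733 ± 1230.3 against 2599 ± 735 CPM. The cartilage transcription factors Sox9 and Sox6 were at 973 ± 215 against 494 ± 94.7 CPM and 54.8 ± 10.9 against 19.2 ± 7.72 CPM. Without the length trend the log2 fold change went from -1.47 to -0.63 for Acan and from -1.37 to -0.50 for Col11a1. It went from -0.98 to -0.71 for Sox9 and from -1.52 to -0.54 for Sox6. 4 members passed when adjusted over the list alone. With the length trend removed the median was -0.31 (adjusted p = 0.0243), while the call was lost without Lama4-/- replicate 1 (adjusted p = 0.158) and without Lama4-/- replicate 3 (0.141). With each library left out the median ranged from -0.73 to -0.11. Osteoblast and adipocyte differentiation did not pass (camera adjusted p = 0.308 and 0.906). Runx2, the transcription factor that starts osteoblast differentiation, was at 168 ± 37.5 against 68.8 ± 8.55 CPM. Sp7, another osteoblast transcription factor, was at 155 ± 30.4 against 128 ± 28.8 CPM, and osteocalcin (Bglap) at 3056 ± 1239.8 against 4366 ± 2436 CPM. Pparg was at 25.4 ± 5.34 against 34.7 ± 12.6 CPM and Adipoq at 637 ± 295 against 640.4 ± 181 CPM. Of these 5 genes, only Runx2 had groups that did not overlap, and its log2 fold change went from -1.29 to -0.55 with the length trend removed. Pericyte and smooth muscle markers fell, with a median of -0.46 over 16 genes (camera adjusted p = 0.0182; adjusted p = 0.565 with an estimated correlation). NG2 (Cspg4) was at 647 ± 179 against 254 ± 59.2 CPM and Abcc9 at 17.9 ± 12.2 against 3.43 ± 1.85 CPM. Mylk was at 84.4 ± 34.5 against 38.4 ± 13.1 CPM and Rgs4 at 22.9 ± 3.44 against 10.5 ± 3.89 CPM. 1 member passed when adjusted over the list alone. That call was lost without wild type replicate 1 (adjusted p = 0.102), without Lama4-/- replicate 3 (0.326) and with limma voom (0.0593), where the medians were -0.60, -0.79 and -0.96. The median was also -1.04 without Lama4-/- replicate 1 and -1.05 with the replicate block, so its size is uncertain. With the length trend removed the median was -0.27 (adjusted p = 0.0414).

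Nuclear genes of oxidative phosphorylation rose in Lama4-/-, 72 of 74 with a positive log2 fold change and a median of 0.45 (camera adjusted p = 4.92e-13; adjusted p = 0.565 with an estimated correlation). Sdhb of complex II was at 94.5 ± 10.7 against 150.2 ± 0.549 CPM. Uqcrc1 and Cyc1 of complex III were at 189.9 ± 32.4 against 308 ± 50.8 CPM and 114 ± 15.1 against 178 ± 18.9 CPM. The ATP synthase subunit Atp5c1 was at 126 ± 14.6 against 211 ± 12.8 CPM. 16 members had an unadjusted p under 0.05, and 0 passed when adjusted over the list alone. Transcripts of this list were short, with a median of 1186 bases, and without the length trend the median was 0.17 (adjusted p = 0.00172). With each library left out it ranged from 0.25, without wild type replicate 2, to 0.62, without wild type replicate 1. Messenger RNAs encoded in the mitochondrial genome went the other way and fell, all 8 tested with a negative log2 fold change and a median of -0.95 (camera adjusted p = 0.0128; adjusted p = 0.651 with an estimated correlation), and -1.19 (adjusted p = 2.97e-06) without the length trend. Of these, mt-Nd2 was at 718 ± 444 against 255 ± 100.2 CPM and mt-Nd5 at 802 ± 388 against 419 ± 162 CPM. The gene mt-Nd4 was at 1112 ± 759 against 335 ± 117 CPM and mt-Nd6 at 176 ± 119 against 52.9 ± 23.4 CPM. Each of these 4 overlaps another gene, so their counts are uncertain. Of the 13 genes of this list only 8 are among the deposited genes, so the others could not be tested. 0 members passed when adjusted over the list alone. The wild type libraries differed among themselves here, with mt-Nd4 at 1739, 269 and 1329 CPM. The call was lost without wild type replicate 1 (adjusted p = 0.155), wild type replicate 3 (0.133) or Lama4-/- replicate 2 (0.259), with medians of -0.74, -0.71 and -0.73. Cytosolic ribosomal protein genes rose by a median of 0.27 over 79 genes (camera adjusted p = 1.01e-04; adjusted p = 0.754 with an estimated correlation). Rplp0 was at 403 ± 58.7 against 638 ± 83.2 CPM and Rpl4 at 433 ± 83.5 against 631 ± 56.4 CPM. Rpl7 was at 65.5 ± 23.5 against 99.5 ± 16.8 CPM and Rpl13 at 13.4 ± 4.96 against 22.4 ± 4.75 CPM. Pseudogene copies make single counts uncertain. 0 of them passed when adjusted over the list alone, and the call was lost without wild type replicate 2 (adjusted p = 0.362) and with the length trend removed, where the medians were 0.06 and 0.02 (adjusted p = 0.601 for the second). Antioxidant genes rose by a median of 0.25 (camera adjusted p = 0.00223; adjusted p = 0.547 with an estimated correlation). The glutathione peroxidase genes Gpx1 and Gpx8 were at 282 ± 45.5 against 541 ± 98.2 CPM and 192 ± 19.5 against 330.3 ± 43.8 CPM. Gpx4 was at 32.5 ± 3.17 against 61.99 ± 9.45 CPM and Gpx7 at 97.3 ± 13.4 against 152 ± 11.04 CPM. 3 of 32 passed when adjusted over the list alone. Their median was 0.14 without wild type replicate 3 and 0.08 without the length trend (adjusted p = 0.343).

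Interferon response genes rose, 31 of 42 with a positive log2 fold change and a median of 0.51 (camera adjusted p = 5.16e-04; adjusted p = 0.565 with an estimated correlation). Irf7, which encodes a transcription factor of the type I interferon response, was at 40.4 ± 9.93 against 111 ± 27.997 CPM. The immunoproteasome subunit Psmb8 was at 29.1 ± 6.26 against 55.7 ± 2.84 CPM. Tetherin (Bst2) was at 59.6 ± 12.6 against 118 ± 49.7 CPM and Ifi27 at 133 ± 16.9 against 202 ± 29.8 CPM. 7 members had an unadjusted p under 0.05 on the higher side and 2 on the lower, and 1 passed when adjusted over the list alone. The median was 0.40 (adjusted p = 0.0167) without the length trend, and the call held when each library was left out in turn. The size of the rise was less stable, at 0.19 without Lama4-/- replicate 1, 0.26 with the replicate block and 0.27 with limma voom.

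Markers of neutrophils and monocytes and of erythroid cells, which the gate should leave out, were higher in Lama4-/-. Neutrophil and monocyte markers rose, all 21 tested with a positive log2 fold change and a median of 2.51 (camera adjusted p = 6.46e-07; adjusted p = 0.565 with an estimated correlation), and 2.27 (adjusted p = 3.33e-06) without the length trend. The calprotectin genes S100a8 and S100a9 were at 15.9 ± 8.76 against 99.5 ± 65.2 CPM and 27.02 ± 19.4 against 155 ± 112 CPM. Lysozyme (Lyz2) was at 16.8 ± 4.69 against 66.4 ± 26.9 CPM. The granule genes Camp and Mmp8 were at 3.01 ± 1.603 against 29.8 ± 21.96 CPM and 1.41 ± 0.781 against 11.3 ± 5.37 CPM. 4 members passed when adjusted over the list alone. The Lama4-/- libraries were uneven, with S100a8 at 155, 116 and 27.7 CPM. Erythroid markers rose, with a median of 0.70 over 20 genes (camera adjusted p = 0.00127; adjusted p = 0.565 with an estimated correlation), and 0.44 (adjusted p = 0.0167) without the length trend. The size depended on single libraries, with a median of 1.43 without wild type replicate 3 and 0.50 without Lama4-/- replicate 1, and was 1.31 with limma voom. Alas2 of haem synthesis was at 44.6 ± 29.8 against 149 ± 68.98 CPM and Bpgm at 34.2 ± 15.2 against 76.5 ± 29.3 CPM. The haemoglobin gene Hbb-bs was at 390.3 ± 343 against 1438 ± 703 CPM, Hbb-bt at 124 ± 112 against 429.7 ± 193 CPM and Hba-a1 at 159 ± 137 against 489 ± 229 CPM. Near-identical copies make the haemoglobin counts uncertain. 0 erythroid members passed when adjusted over the list alone, and with mitochondrial, ribosomal, haemoglobin and immunoglobulin genes left out the list no longer passed (adjusted p = 0.0649), though its median was still 0.63. Marker lists of endothelial, Schwann, muscle, B lineage, megakaryocyte and macrophage cells did not pass, and of the T and NK cell list only 3 genes were tested. Of the blood lineage lists that did not pass, the median was -0.81 for megakaryocyte, 0.07 for macrophage and 0.09 for B lineage markers.

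The most abundant markers of those other cell types were read as single genes. The endothelial genes Eng and Ramp2 were at 16.96 ± 5.48 against 14.04 ± 7.202 CPM and 12.8 ± 8.46 against 11.7 ± 5.04 CPM. The Schwann and neural genes Pmp22 and Ncmap were at 283 ± 28.9 against 284 ± 43.2 CPM and 171 ± 19.9 against 179 ± 46.1 CPM. The muscle genes Tnni2 and Eno3 were at 32.7 ± 4.55 against 36.6 ± 8.03 CPM and 16.2 ± 5.24 against 26.8 ± 8.51 CPM. Of B and plasma cell genes, Xbp1 was at 318 ± 25.8 against 429 ± 58.8 CPM and Sdc1 at 100.3 ± 40.8 against 100.3 ± 0.392 CPM. The T cell genes Tcf7 and Lck were at 25.9 ± 6.57 against 50.3 ± 17.9 CPM and 1.55 ± 0.905 against 2.29 ± 2.72 CPM. The megakaryocyte genes Rab27b and Itgb3 were at 13.6 ± 2.01 against 10.1 ± 6.69 CPM and 11.7 ± 7.27 against 2.79 ± 3.03 CPM. Of the osteoclast and macrophage list, Nfatc1 was at 532 ± 226 against 283 ± 75.9 CPM, beside Vcam1. Of the pericyte list, Ndufa4l2 was at 73.1 ± 20.3 against 91.9 ± 30.1 CPM, beside Cspg4. None of these genes passed the adjustment over all genes in the edgeR test, while Cspg4 passed with DESeq2 (adjusted p = 0.000681).

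**Figure D3:**
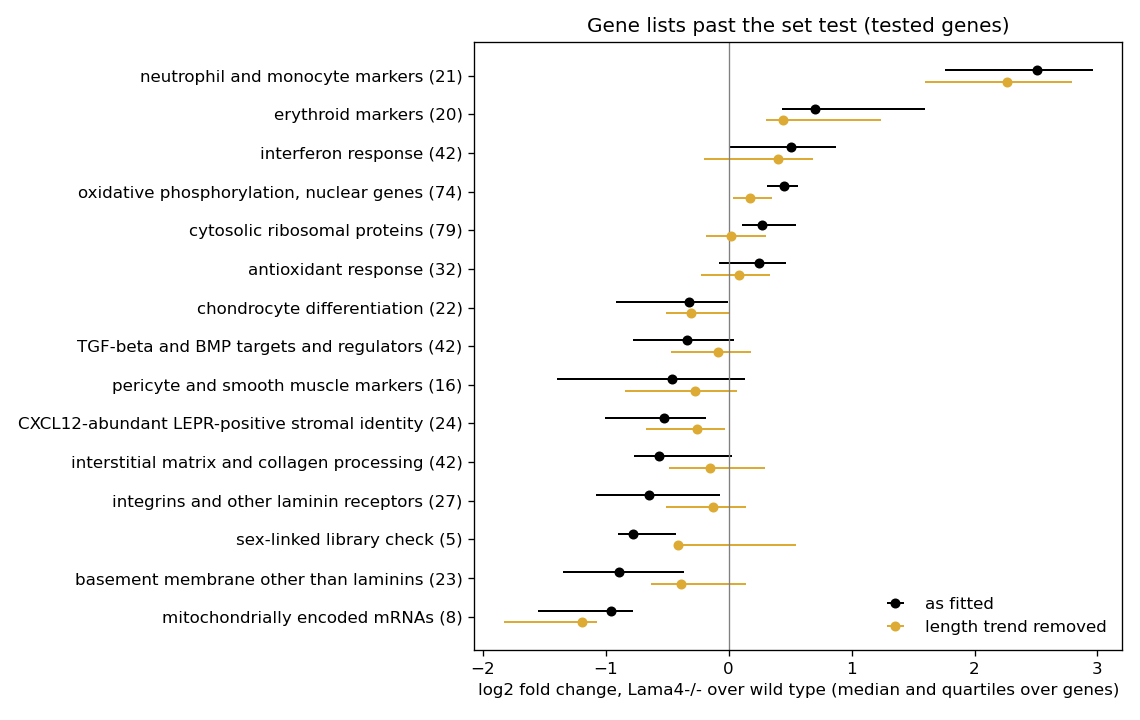
Each row is a gene list past the set test, with its number of tested genes; points give the median log2 fold change of Lama4-/- over wild type and bars the quartiles over genes, in black as fitted and in yellow with the transcript length trend removed. Neutrophil and monocyte markers have the highest median, 2.51, and mitochondrially encoded mRNAs the lowest, -0.95.

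Genes of the sort gate checked the cells. The list did not pass (camera adjusted p = 0.145, median -0.93), nor with the length trend removed (adjusted p = 0.313, median -0.40). The positive marker Itgav (CD51) was at 114 ± 22.5 against 59.2 ± 14.3 CPM. Of the negative markers, Ptprc (CD45) was at 1.82 ± 2.08 against 0.727 ± 1.26 CPM and Pecam1 (CD31) at 1.72 ± 0.333 against 0.319 ± 0.377 CPM. Ly6a (SCA1) was at 11.7 ± 4.004 against 10.5 ± 1.65 CPM and Cd44 at 121 ± 43.8 against 63.6 ± 15.98 CPM. Removing the length trend took the log2 fold change from -0.94 to -0.12 for Itgav and from -0.93 to -0.32 for Cd44. It went from -1.32 to -0.80 for Ptprc, from -2.40 to -2.35 for Pecam1 and from -0.16 to -0.48 for Ly6a. The sex-linked check genes fell as a list, all 5 tested with a negative log2 fold change and a median of -0.77 (camera adjusted p = 0.0281; adjusted p = 0.565 with an estimated correlation). Xist was at 87.2 ± 52.9 against 51.1 ± 24.9 CPM. Among Y-linked genes Ddx3y was at 80.4 ± 9.86 against 23.4 ± 7.92 CPM and Eif2s3y at 20.2 ± 1.07 against 14.98 ± 3.38 CPM. Uty was at 5.63 ± 1.36 against 3.03 ± 2.19 CPM and Kdm5d at 4.41 ± 3.85 against 3.74 ± 5.33 CPM. Tsix, antisense to Xist, was below the filter. 1 member passed when adjusted over the list alone. Xist and Ddx3y were both counted in each of the 6 libraries, and the labels do not give the sex of the mice or the number per library. Their call was lost without wild type replicate 1 (adjusted p = 0.102), without Lama4-/- replicate 1 (0.104) or 2 (0.0528), with medians of -0.67, -0.72 and -1.55. It was also lost with the length trend removed, at a median of -0.41 (adjusted p = 0.282).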

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

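Except for the length trend removal and the counts at an unadjusted p, the alternatives were set before the data were examined. Lama4 alone was called in edgeR with DESeq2 size factors, with a filter of 5 CPM in 3 libraries, with dominant gene classes left out and at an adjusted p of 0.10. The count of calls was 0 with upper-quartile scaling, without robust moderation, with limma voom, with the length trend removed and against a fold of 1.5, and 0 or 1 with each library left out, 1 only without Lama4-/- replicate 3. Without a filter it was 12, of which 1 gene was higher and 11 lower, and with DESeq2 it was 741, 173 higher and 568 lower; the cause was not tested. The adjusted p of Lama4, main value 0.0497, was 0.0550 with upper-quartile scaling, 0.0507 without robust moderation, 0.0751 with the length trend removed, 0.160 with limma voom and 0.0482 to 0.593 with each library left out, while its counts stayed 0 in Lama4-/-. With the replicate block the count of calls was 0, with 0 lower, Lama4 had an adjusted p of 0.3005 and 16 lists passed. The replicate numbers were not taken as pairs, since deviations of same-numbered libraries correlated at 0.040, 0.132 and 0.054, although every library correlated best with its own number, a hint from the data and not the design. At an unadjusted p, 1170 genes passed with the length trend removed, 1184 without wild type replicate 3 and 2816 with DESeq2, against 1851; the share of higher genes among them was 34.8%, 50.5% with upper-quartile scaling and 61.0% with the length trend removed. The number of lists past the set test was 10 with the length trend removed, 12 with dominant classes left out, 14 to 16 under the other scalings, filters and tests, and 11 to 17 with each library left out, of which 6 to 7 were higher and 5 to 11 lower, the 5 without wild type replicate 1. It was 0, with 0 higher and 0 lower, with an estimated correlation and with fry. The mitochondrial and ribosomal lists had no genes once dominant classes were left out, and DESeq2 has no list test here. None of the 15 lists changed direction under another scaling, which is a weak check, since a scaling moves all genes of a library alike.

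Of 108 named genes tested, 93 kept their direction under every alternative run and 15 did not, none of the 15 called in any edgeR fit with the filter. With the length trend removed the log2 fold change reversed to -0.24 for Pmp22, -0.28 for Adipoq, 0.40 for Rab27b, -0.19 for Tnni2, -0.16 for Ncmap, 0.55 for Kdm5d, 0.0248 for Cxcl12 and 0.80 for Xist. Lck reversed to -0.72 with the replicate block and -1.29 with limma voom. With each library left out the value ranged over -0.96 to 1.17 for Lck, -0.46 to 0.56 for Ramp2, -0.13 to 0.0834 for Pmp22, -0.21 to 0.37 for Sdc1, -0.24 to 0.45 for Adipoq, -7.52 to 0.15 for Ptprc, -0.71 to 0.0697 for Eng, -0.0128 to 0.32 for Tnni2, -0.23 to 0.73 for Il7, -0.17 to 0.20 for Ncmap, -2.68 to 0.59 for Kdm5d and -0.32 to 0.17 for Ly6a. DESeq2 put 53 of the other 107 genes past the threshold, all in the same direction. Thinned to 6263830 counts each, the libraries gave 1 called gene, 1823 at an unadjusted p under 0.05 and 15 lists. The unequal library totals alone therefore did not set these results.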

Other observations

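The tests of RNA integrity, of long matrix genes and of the length trend behind single lists were chosen after the results were seen. The tests of depth, flanking DNA, other splits and the time of day were written before their own results were seen. Those of depth and time of day address patterns found in these data.

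The clearest pattern across genes was that long transcripts were lower in Lama4-/-. It was not limited to matrix genes. Without the matrix, basement membrane, laminin and laminin receptor lists Spearman's rho of the log2 fold change with length was -0.458. That left 14357 of 14458 genes, so rho could hardly have moved, but the trend was present outside those lists. With every library thinned to the smallest total rho was -0.504. Thinning keeps the expected share of each gene in its library, so it addresses only the noise of low counts. Another effect of sequencing depth cannot be excluded by it. Outside every fixed list rho was -0.454 and all 9 library pairs were negative, as less intact RNA or shorter cDNA in the Lama4-/- libraries would give; a lower level of long transcripts in the Lama4-/- cells would give the same and stays open. The trend may account for the fall of the interstitial matrix list, whose median went from -0.57 (quartiles -0.77 to 0.0237) to -0.15 (-0.48 to 0.30) when it was removed, losing the call because the shift itself shrank. For the basement membrane list the median went from -0.89 (quartiles -1.35 to -0.36) to -0.39 (-0.63 to 0.14). It passed after removal at the preset correlation, and an estimated correlation was not tried after removal. Its quartiles then spanned 0, so genotype and length trend cannot be told apart for this list. For oxidative phosphorylation genes the median went from 0.45 to 0.17 (quartiles 0.0368 to 0.35) with the trend removed, past the threshold at the preset correlation. Without wild type replicate 2 and with the trend kept the median was 0.25. The removal fitted a single curve per library, while rho was -0.621 among genes with a mean CPM above 32 and -0.461 among all tested genes. A remainder of the length trend and a rise with genotype therefore cannot be told apart for this list.

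Neutrophil and monocyte markers were higher in Lama4-/- although the gate removed CD45-positive cells. The length trend does not explain this, since the median was 2.27 with it removed, from 2.51, with quartiles of 1.601 to 2.794. S100a9, S100a8 and Lyz2 were at 155, 99.5 and 66.4 CPM in Lama4-/-, and 2 of the 27 genes listed are also in another list. Ptprc, which encodes the sorted marker, was at 0.727 CPM, with 0 counts in 2 of the 3 Lama4-/- libraries. RNA or cells of the myeloid lineage in the libraries and expression of these genes by the stromal cells were not tested against each other, and both stay open.

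The clock-output gene Dbp was higher in every Lama4-/- library, and mice of the 2 genotypes may have been sampled at different times of day. Of 9 tested clock genes in phase with Dbp 3 were higher, and of 5 of the opposite phase 4 were lower. By the bound set beforehand this would exclude the time of day, but 10 of the 14 genes have transcripts above the median length of tested genes, and with the length trend removed 6 of the 9 were higher and 4 of the 5 lower. Time of day and genotype therefore cannot be told apart for Dbp, with the length trend keeping the question open.

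The other splits of the 6 libraries into 3 and 3 gave at most 0 called genes against 1 in the real split, 638 genes at an unadjusted p under 0.05 against 1851, and 13 lists against 15. In each of these 3 counts 1 of the 10 splits, the real one, was as large, but 10 splits cannot give a share under 0.05. The split with 13 lists set wild type replicates 1 and 2 and Lama4-/- replicate 2 against the others.

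Genes near Lama4 could carry DNA of the embryonic stem cell strain used for targeting. Within 20 Mb, Lama4 itself left out, 12 of 156 tested genes (7.69%) had an unadjusted p under 0.05, against 1838 of 14308 elsewhere (12.8%). The odds ratio was 0.565 (95% interval 0.285 to 1.02) and the one-sided Fisher's exact p for an excess was 0.984, so no excess was seen near Lama4. The share elsewhere includes genes moved by the length trend. The test therefore cannot say whether any of the 12 nearby genes stems from flanking DNA. At an adjusted p under 0.05 no gene but Lama4 was called, so that form of the test had nothing to count (one-sided Fisher's exact p = 1).

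Each library held counts of both Xist and the Y-linked gene Ddx3y; Ddx3y was at 85.9, 69.01 and 86.3 CPM in wild type and 23.9, 15.3 and 31.1 CPM in Lama4-/-. The labels do not give the sex of the mice or the number per library. With the length trend removed the log2 fold change was 0.80 for Xist, -1.39 for Ddx3y, -0.41 for Eif2s3y, -0.44 for Uty and 0.55 for Kdm5d. Libraries of mixed sex and mixing between libraries were not tested and stay open. The Ddx3y difference and the fall of the sex-linked list are therefore not read as effects of genotype. A share of each sex that differs between the genotypes could also bear on other genes and lists, and the labels cannot exclude it.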
